A study of Mus with 3 samples.

How the data were processed

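Whole lungs of 3 groups of female mice were measured with the 10x Chromium 3′ v3 kit, per the labels' protocols, as 1 library each of WT PBS, WT OVA and DJ-1 KO OVA cells, every library pooled over 3 mice. The deposited values are raw UMI counts per gene and barcode, made with software version 3.1.0 per the file headers. Reads were processed with Cell Ranger and STAR on the mm10 build, per the submitters' processing notes, which give no annotation release. The barcodes had been called as cells before deposit, since no barcode holds fewer than 500 UMIs. The title of the WT PBS library names an ovalbumin challenge, but its treatment label and library name say PBS, and the group follows the latter.

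From the 27998 genes of the matrices, cells with at least 200 genes and at most 20% mitochondrial UMIs were kept, and doublets were removed per library with Scrublet in scanpy 1.11.5 (expected rate 0.06). It removed 76, 200 and 9 barcodes of WT PBS, WT OVA and DJ-1 KO OVA, with score limits of 0.258, 0.218 and 0.488. The libraries were clustered together without integration (log1p of counts scaled to 10000, 2000 highly variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Clusters were named from 38 fixed marker lists and from a Rag1 and Dntt list that was added outside them. Close calls were split into sub-clusters. A name needed a mean log2 marker score of at least 1 and at least 3 markers detected in 10% of cells, and is given as "-like". A cluster stayed unnamed where its cells held few UMIs and none of its markers was among its 10 leading genes. It also stayed unnamed where those 10 genes held more than 1 marker of another class and fewer of its own. Other tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

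WT OVA was compared with WT PBS, and DJ-1 KO OVA with WT OVA, so WT OVA serves both comparisons. With 1 library per group no test was possible. UMIs were summed per library and class and scaled to CPM. Classes needed at least 50 cells in both libraries. Of 23 gene lists fixed before the data were examined, with 449 members, 439 were found in the matrices, 2 of them through synonyms. Each list is given by the median log2 ratio of members with at least 20 UMIs, by members past 1.5-fold, and by its percentile among 10000 random lists matched on expression. The intervals of list medians come from 200 Poisson draws. The lists are type 2 cytokines, epithelial alarmins, eosinophil chemokines, eosinophil granule genes, mucous genes, alternative activation, NRF2 targets, mTORC1 pathway, autophagy, progenitor genes, transitional state, surfactant, interferon response, inflammatory and NF-kB genes, MHC class II, glycolysis, oxidative phosphorylation, cell cycle, immediate early genes, heat shock, extracellular matrix, T helper 2 and regulatory T genes, and immunoglobulin constant genes. The last is void, since 0 of its 8 members are among the genes used.

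Named genes were fixed by a rule written before the data were examined, which takes Park7, members of the lists, cell type markers and, in each of 5 classes per comparison, the 3 genes with the highest and the 3 with the lowest ratio. Ranked genes needed at least 100 UMIs over both libraries and a class CPM of at least 0.5 of that in all other cells. Mitochondrial, ribosomal, haemoglobin and immunoglobulin genes and unnamed models were left out of the ranking. Genes named outside this rule, Gm10093, Gm10036, Gm13157, Rpl11 and Hdac1, were chosen after their values were seen. A gene that the rule takes in CD4 T-like cells is not reported here. A ratio against 0 UMIs is given as a bound against 3 UMIs per library.

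The ratio, interval and list steps were tested on simulated Poisson counts with 200 changed genes, drawn around a shared profile. No cells, clusters, doublets or shared barcodes were simulated, so the test does not bear on filtering, clustering or naming. For WT OVA over WT PBS (9626 genes) 96.3% of intervals held the true ratio and 5% of unchanged lists fell outside the central limits, and for DJ-1 KO OVA over WT OVA (9234 genes) 96.3% and 4.5%. Intervals excluded no difference for 84% of simulated 2-fold higher genes in each comparison, and for 67.4% and 63.0% of 2-fold lower genes. Alternatives covered filters, doublets, clustering, scaling, weighting of cells, depth and list members. Further alternatives, on barcodes that occur in more than 1 library, a doublet score limit of 0.25, shares outside the Rag1 and cycling clusters and pooled club-like and goblet-like cells with and without the smaller cells, were chosen after seeing the data, as were the reading of WT OVA levels beside those of B cell-like cells and the ratios outside cluster 16. Chromosomes of genes come from the RefSeq table of GRCm38.p6.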

Results

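Single-cell RNA was measured in whole lung of female mice aged 6-12 weeks. There were 3 groups, wild-type mice challenged with PBS (WT PBS), wild-type mice challenged with ovalbumin, a common model allergen (WT OVA), and ovalbumin-challenged mice lacking DJ-1, the redox-sensitive protein encoded by Park7 (DJ-1 KO OVA). Each group was 1 library of cells pooled over 3 mice, so no difference between groups has a replicate check. The libraries held 4556, 6406 and 4666 barcodes with 26548669, 24438516 and 17339386 UMIs (unique molecules) in WT PBS, WT OVA and DJ-1 KO OVA. After filtering, 4138, 5892 and 4497 cells remained, with medians of 3852.5, 2050 and 1634 UMIs per cell. Brackets hold 95% intervals, exact Poisson for CPM (UMIs scaled to the total of the library or class), exact conditional binomial for ratios of CPM and Clopper-Pearson for shares. They cover counting error only.

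Park7 was detected in every library. It stood at 134 CPM in WT PBS (129 to 139), 100.2 CPM in WT OVA (96.1 to 104) and 21.2 CPM in DJ-1 KO OVA (19.0 to 23.5). The DJ-1 KO OVA level was 0.211 (0.189 to 0.236) of the WT OVA level, and WT OVA stood at 0.748 (0.709 to 0.789) of WT PBS. Park7 was lower in DJ-1 KO OVA than in WT OVA in CD4 T-like cells, at 0.110 (0.0704 to 0.166), in alveolar type 2-like cells, at 0.231 (0.174 to 0.303), and in club-like cells, at 0.243 (0.159 to 0.358). Remaining UMIs occurred in each of these classes, and a 3′ tag outside the deleted part of the gene would still be counted.

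A total of 372 cell barcodes occurred in both the WT PBS and the DJ-1 KO OVA library, where independent draws would give 3.13. In 306 of these pairs the WT PBS cell was the smaller, with a median of 4.91% of the UMIs of its DJ-1 KO OVA partner. In the other 66 the DJ-1 KO OVA cell was the smaller, at a median of 2.15%. Over barcodes shared between any libraries, the smaller cells kept numbered 299 in WT PBS, 69 in DJ-1 KO OVA and 5 in WT OVA. Of those in WT PBS, 70 were unnamed, 69 alveolar macrophage-like, 48 goblet-like, 34 fibroblast-like, 28 club-like and 14 mesothelial-like. Of those in DJ-1 KO OVA, 29 were club-like. Values without the smaller cells are given beside several ratios and shares below.

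**Figure D1:**
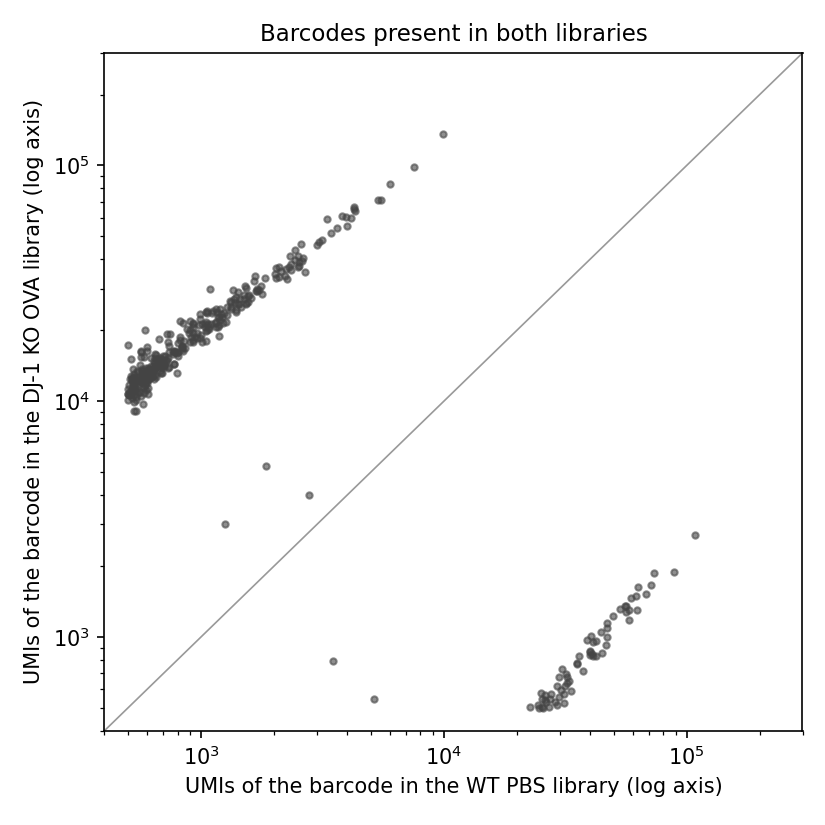
Each point is 1 of the 372 barcodes found in both the WT PBS and the DJ-1 KO OVA library. The horizontal log axis gives its UMIs in WT PBS, the vertical log axis its UMIs in DJ-1 KO OVA, and the line marks equal totals. Most points lie in a pair of narrow bands, 306 above the line and 66 below it.

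CD4 T-like cells made up 16.1% (14.96 to 17.2) of WT PBS, 19.6% (18.6 to 20.6) of WT OVA and 21.0% (19.8 to 22.2) of DJ-1 KO OVA. That class also held Cd8a, at 132 CPM in WT OVA against 302 CPM in CD8 T-like cells. With each library clustered on its own, CD4 T-like cells numbered 181 of 4138, 886 of 5892 and 499 of 4497. CD8 T-like cells then numbered 694, 512 and 0, so the order of the CD4 T-like shares depends on the clustering. No cluster carried the markers of eosinophils, the granulocytes that the series title names. Over all kept cells Prg2, an eosinophil granule gene, had 6, 17 and 1 UMIs in WT PBS, WT OVA and DJ-1 KO OVA, and Ccr3, the eotaxin receptor, had 15, 31 and 15. Prg2 was also among the leading genes of the plasma cell-like cluster, so its UMIs are not read as a measure of eosinophils. Cluster 25, with alveolar type 2 markers and a median of 667 UMIs per cell, was kept unnamed. It held 1.96% of WT PBS, 0.119% of WT OVA and 0.689% of DJ-1 KO OVA cells, and 69 of its 81 WT PBS cells were smaller members of pairs. A cluster led by Rag1 and Dntt, genes of lymphocyte progenitors, held 17.3% (16.2 to 18.4) of DJ-1 KO OVA, 0.153% of WT OVA and 0.701% of WT PBS, and it takes part in every share of that library. Arpp21 and Ccr9 were also among its leading genes, and its next-best score was that of CD8 T cells, at 2.04. Whether these cells belong to the lung was not tested, which bears on the shares and on the T cell and cycling values of DJ-1 KO OVA.

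**Figure D2:**
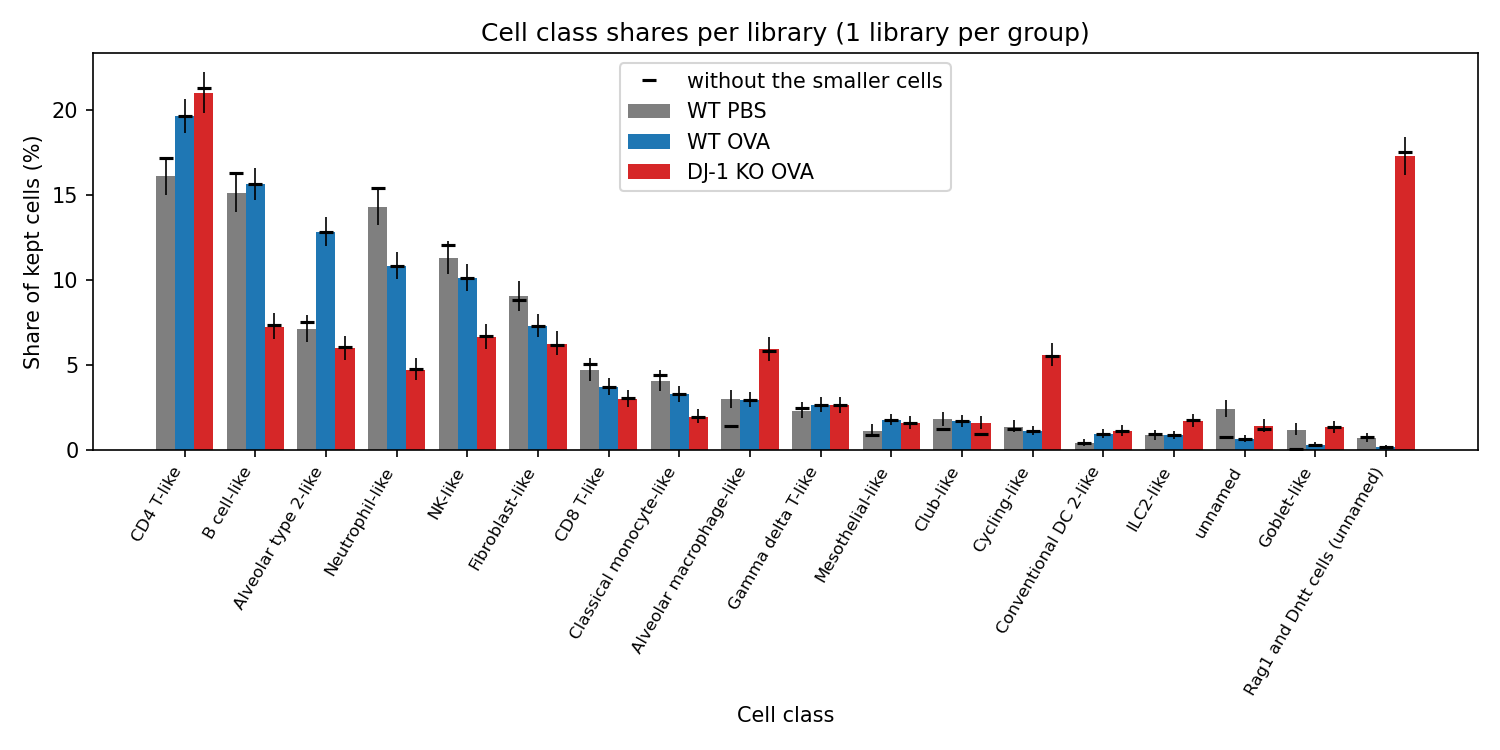
Bars give the share of kept cells in percent (vertical axis, from 0) for each cell class with at least 50 cells in any library (horizontal axis), in WT PBS, WT OVA and DJ-1 KO OVA. Lines are 95% Clopper-Pearson intervals, and black dashes give the share without the smaller cells of barcodes that occur in more than 1 library. Alveolar macrophage-like cells made up 5.92% of DJ-1 KO OVA and 2.92% of WT OVA.

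The comparison of WT OVA with WT PBS sets ovalbumin-challenged beside PBS-challenged wild-type lung. Mucous and IL-13 responsive epithelial genes stood higher in WT OVA. Over all kept cells Clca1, a goblet cell product, was 5.46-fold (5.30 to 5.62) higher, and 19.8-fold (18.8 to 20.9) without the smaller cells of shared barcodes. Muc5ac, a gel-forming airway mucin, was 5.32-fold (4.43 to 6.43) higher, and 22.9-fold (16.1 to 33.8) without those cells. Retnla, which encodes a secreted resistin-like protein, was 34.9-fold (31.4 to 39.0) higher in alveolar type 2-like cells and 62.5-fold (54.1 to 72.6) without them. In CD4 T-like cells Il1rl1, the IL-33 receptor, was 5.12-fold (3.81 to 6.998) higher.

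Over all kept cells the mucous list had 14 of 18 members above 1.5-fold and 1 below, and its median log2 ratio was 1.31 (1.14 to 1.44), percentile 100 among 10000 random lists of matched expression. Without the smaller cells the median was 2.04. With cells weighted alike the median turned to -0.95, with Clca1 at -1.09 and Muc5ac at -1.22, and after thinning every cell to 1000 UMIs it was -0.77, with -0.77 and -1.30. Chil4, a chitinase-like protein, was 1.18-fold (1.13 to 1.22) higher over all kept cells, but 18.6-fold (16.6 to 20.9) without the smaller cells, and its log2 ratio was -3.79 with cells weighted alike and -3.50 after thinning. Both settings give small cells as much weight as large ones. Of the 49 goblet-like cells of WT PBS, 48 were smaller members of pairs, and neither setting was computed without them. In alveolar type 2-like cells the same list had a median of 2.64 (2.23 to 3.02), percentile 100, with 9 of 10 members above 1.5-fold and 1 below. Of those 9 members, 5 (Bpifb1, Clca1, Muc5b, Reg3g and Tff2) lay below their level in B cell-like cells of WT OVA and are read as background. There Slc26a4, the anion exchanger pendrin, was 3.79-fold (2.98 to 4.88) higher and Ly6i was 19.3-fold (10.6 to 39.2) higher. Cluster 16, 21 of the 755 cells of this class in WT OVA and 2 of 294 in WT PBS, held 42.4% of its Retnla, 43.3% of its Slc26a4 and 39.7% of its Ly6i UMIs in WT OVA. Outside that cluster the ratios of WT OVA to WT PBS were 29.6 for Retnla, 2.27 for Slc26a4 and 13.4 for Ly6i. The genes ranked lowest in that class were Scfd1 at 0.359 (0.264 to 0.483), Nnat at 0.409 (0.331 to 0.505) and Hist1h2bc at 0.436 (0.355 to 0.534) of the WT PBS level.

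In club-like cells, 99 in WT OVA and 74 in WT PBS, Chil4 was 25.8-fold (21.7 to 30.9) higher, Clca1 16.7-fold (15.6 to 18.0) higher and Saa3, an acute-phase protein, 23.7-fold (13.4 to 46.2) higher. Without the smaller cells, Chil4 was 58.1-fold higher, and Saa3, at 0 UMIs in the remaining 46 WT PBS cells, at least 91.5-fold higher against a floor of 3 UMIs per library. Cyp2a5, a cytochrome P450, stood at 0.217 (0.181 to 0.259), the airway defence protein gene Bpifa1 at 0.314 (0.307 to 0.321) and Hist1h2bc at 0.320 (0.234 to 0.434) of the WT PBS level. The mucous list had a club-like median of 0.94 (0.82 to 1.21), percentile 100, with 11 of 16 members above 1.5-fold and 2 below. Club-like and goblet-like cells pooled gave a Chil4 log2 ratio of -0.36 and a list median of 0.78. Without the smaller cells, which are 48 of the 49 goblet-like cells of WT PBS, the pooled values were 3.52 and 1.22. Clustering each library on its own turned all 3 values, Chil4 to -4.83, Clca1 to -6.27 and the list to -2.46. Chil4 also turned to -2.44 with at most 10% mitochondrial UMIs and -1.63 at Leiden resolution 2, and the list stood at -0.088 with that mitochondrial limit, 0.25 with doublets kept and 1.52 after thinning to 1000 UMIs.

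In alveolar macrophage-like cells of WT OVA Ch25h, which makes 25-hydroxycholesterol, was 5.66-fold (4.35 to 7.47) higher, and 14.2-fold (9.38 to 22.6) without the smaller cells. The chemokine gene Ccl4 was 4.47-fold (3.86 to 5.18) higher and Il6 4.47-fold (3.65 to 5.53) higher. The scavenger receptor gene Marco stood at 0.289 (0.217 to 0.382), Erdr1 at 0.296 (0.224 to 0.390) and Angptl4, an inhibitor of lipoprotein lipase, at 0.299 (0.223 to 0.398) of the WT PBS level. The alternative activation list had a median of 0.35 (0.14 to 0.67), percentile 99.2, with 4 of 11 members above 1.5-fold and 1 below, and a median of 1.38 without the smaller cells. Ccl17, a chemokine for T helper 2 cells, stood at 270.1 CPM in WT PBS and 421 CPM in WT OVA. All of its WT PBS UMIs in this class lay in the smaller cells, and without them it was at least 131-fold higher in WT OVA. Eosinophil chemokine genes had a median of 0.42 (0.34 to 0.59), percentile 99.6, with 2 of 8 members above 1.5-fold and 2 below, and 1.67 without the smaller cells. Eosinophil granule and activation genes, among them the alveolar macrophage markers Ear1, Ear2 and Siglecf, had a median of -0.52 (-0.80 to -0.067), percentile 0.595. Ccl24 stood at 0.426 (0.323 to 0.560) of the WT PBS level with all cells and was 12.9-fold (4.88 to 48.3) higher without the smaller cells. With cells weighted alike, log2 ratios turned to -0.11 for Ch25h, -2.59 for Ccl17 (-1.95 after thinning), -0.60 for alternative activation and -0.48 for eosinophil chemokines, and to 0.13 for eosinophil granule genes. In WT PBS this class lay in cluster 11 (72 cells, 66 of them smaller members of pairs) and cluster 17 (51 cells), and in WT OVA mostly in cluster 17 (132 of 172). Values with cells weighted alike or thinned were not computed without the smaller cells.

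Among CD4 T-like cells, Areg, an EGF-family ligand, was 5.45-fold (4.10 to 7.35) higher in WT OVA and Lrrc32, which binds latent TGF-β on regulatory T cells, 4.33-fold (2.85 to 6.74) higher. Wbscr22 stood at 0.389 (0.236 to 0.621), Mrpl21 at 0.430 (0.318 to 0.575) and Dapl1 at 0.436 (0.352 to 0.539) of the WT PBS level. Wbscr22 and Mrpl21 were lower in all 6 classes that could be compared, with median log2 ratios of -1.31 and -0.86. Areg was higher in all 5 of its classes, at a median of 1.28, so these 3 differences are not particular to CD4 T-like cells. T helper 2 and regulatory T genes had a median of 0.74 (0.67 to 0.87), percentile 100, with 10 of 16 members above 1.5-fold and 0 below, with Foxp3, the regulatory T cell factor, 4.21-fold (3.20 to 5.60) higher. Cluster 14, which Foxp3 and Il1rl1 help lead, held 20 CD4 T-like cells of WT PBS and 100 of WT OVA, and sub-cluster 0.1, which Dapl1 leads, 217 and 15. In fibroblast-like cells Ptx3, a secreted pentraxin, was 5.52-fold (4.01 to 7.75) higher, Smpd3, a neutral sphingomyelinase, 5.20-fold (3.30 to 8.49) higher and Postn, the matricellular protein periostin, 4.28-fold (3.25 to 5.70) higher. Fdps, of the mevalonate pathway, stood at 0.266 (0.153 to 0.440), Glod4 at 0.425 (0.267 to 0.660) and the co-chaperone gene Dnajb11 at 0.457 (0.359 to 0.578). Ccl11, which encodes eotaxin, was 1.88-fold (1.58 to 2.26) higher in fibroblast-like cells. Their eosinophil chemokine list had a median of 0.26 (-0.23 to 0.54), percentile 96.5, with 3 of 8 members above 1.5-fold and 2 below. It stood at 0.95 with at most 10% mitochondrial UMIs, 0.91 over members past the background rule, 0.75 with doublets kept and 0.70 with a doublet score limit of 0.25, and at -0.19, within the interval, with cells weighted alike. Matrix and remodelling genes had a median of 0.011 (-0.021 to 0.071), percentile 61.3.

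Type 2 cytokine genes over all kept cells had a median of 1.00 (0.83 to 1.17), percentile 100, with 4 of 5 members above 1.5-fold and 1 below. Areg was 2.13-fold (2.002 to 2.27) higher, Il10 3.04-fold (2.20 to 4.25) higher and Il5, the eosinophil growth factor, 1.69-fold (1.12 to 2.58) higher, while Il13 stood at 0.599 (0.259 to 1.31), within counting error of no difference. Il4 had 9 UMIs in WT PBS and 7 in WT OVA. In alveolar type 2-like cells, NRF2 targets and antioxidant enzymes had a median of 0.10 (0.049 to 0.19), percentile 42.4, mTORC1, PI3K and AKT pathway genes 0.017 (-0.080 to 0.13), percentile 22.0, autophagy and mitophagy genes -0.012 (-0.082 to 0.12), percentile 5.81, progenitor genes 0.22 (0.12 to 0.40), percentile 92.9 and epithelial alarmins and their receptors 0.15 (-0.12 to 0.32), percentile 68.7. Transitional state genes had a median of 0.30 (0.059 to 0.45), percentile 97.54, or -0.19 with cells weighted alike, and surfactant and lipid genes -0.092 (-0.12 to 0.021), percentile 0.20. Immediate early genes, which tissue dissociation can induce, had a median of 0.75 (0.71 to 0.80), percentile 100, with 14 of 19 members above 1.5-fold and 0 below.

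Shares of cells also differed between these libraries. Alveolar type 2-like cells made up 12.8% (12.0 to 13.7) of WT OVA and 7.10% (6.34 to 7.93) of WT PBS, and neutrophil-like cells 10.8% (10.0 to 11.6) and 14.3% (13.2 to 15.4). Conventional DC 2-like cells made up 0.9504% (0.719 to 1.23) of WT OVA and 0.411% (0.239 to 0.657) of WT PBS. Goblet-like cells made up 0.272% of WT OVA and 1.18% of WT PBS, but 0.272% and 0.0260% without the smaller cells. Their log2 ratio with all cells was -2.12, and -1.19 with at most 10% mitochondrial UMIs, -1.14 with doublets kept and -0.32 with each library clustered on its own. Alveolar macrophage-like cells made up 2.92% and 2.97%, or 2.92% and 1.41% without them. Median UMIs per kept cell were lower in WT OVA than in WT PBS, which can shift shares through the limit on genes per cell.

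The comparison of DJ-1 KO OVA with WT OVA sets challenged lung without DJ-1 beside challenged wild-type lung. Type 2 and IL-13 linked genes stood higher in DJ-1 KO OVA. Over all kept cells Il13 was 20.4-fold (11.1 to 41.6) higher, from 11 UMIs in WT OVA to 169, and Chil4 was 24.6-fold (23.9 to 25.3) higher. In alveolar macrophage-like cells Arg1, the arginase of alternatively activated macrophages, was 52.1-fold (32.4 to 89.8) higher and Ccl24, an eotaxin, 48.7-fold (39.7 to 60.4) higher. Retnla was 12.7-fold (12.5 to 12.95) higher in alveolar type 2-like cells, and Ccl11 3.96-fold (3.47 to 4.52) higher in fibroblast-like cells.

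The mucous list over all kept cells had 20 of 21 members above 1.5-fold and 0 below, with a median log2 ratio of 1.62 (1.51 to 1.80), percentile 100. Clca1 was 3.30-fold (3.25 to 3.34) higher and Muc5ac 3.68-fold (3.37 to 4.02) higher. Without the smaller cells the log2 ratios were 1.73 for Clca1 and 1.88 for Muc5ac and the list median 1.62. Leaving out both cells of every shared barcode turned them to -1.35, -1.29 and -1.13, but it removes the larger DJ-1 KO OVA partner cells and takes club-like cells from 71 to 9 and goblet-like cells from 60 to 20. The type 2 cytokine list had a median of 1.12 (0.88 to 1.36), percentile 100, with 4 of 6 members above 1.5-fold and 0 below. Il4 was 9.28-fold (4.18 to 24.3) higher, Il10 2.78-fold (2.27 to 3.41) and Il5 1.71-fold (1.21 to 2.42). In ILC2-like cells, innate lymphocytes that make type 2 cytokines, Il13 was 9.31-fold (3.79 to 29.6) higher while Il5 stood at 0.616 (0.400 to 0.945) of the WT OVA level.

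**Figure D3:**
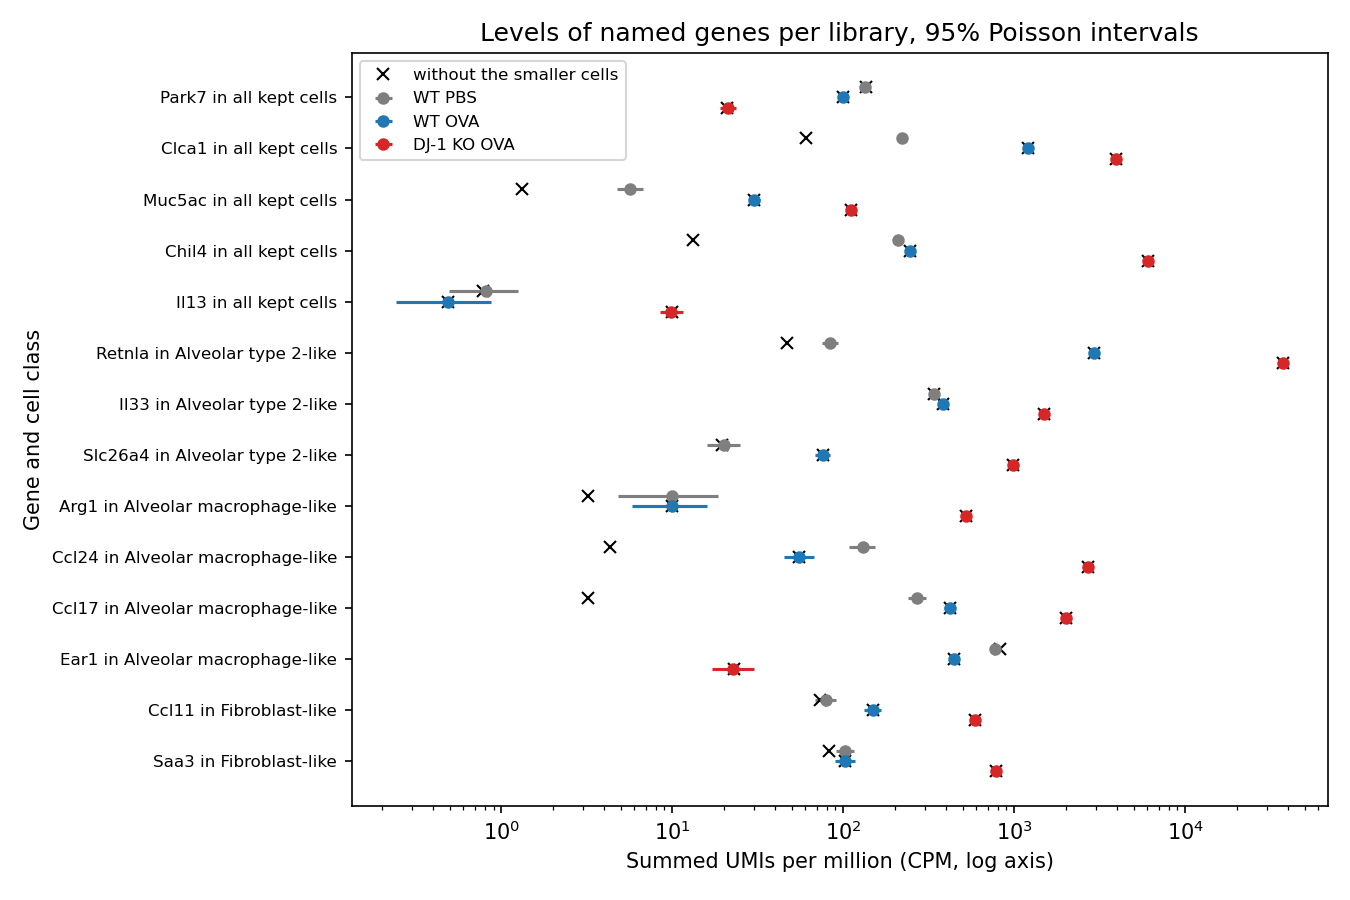
Points give summed CPM (horizontal log axis) of named genes in the class given beside each (vertical axis), for WT PBS, WT OVA and DJ-1 KO OVA, with 95% Poisson intervals. Crosses give the level without the smaller cells of barcodes that occur in more than 1 library, and a level under 3 UMIs is drawn at 3 UMIs. Arg1 in alveolar macrophage-like cells stood at 10.0 CPM in WT OVA and 523 CPM in DJ-1 KO OVA.

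Alveolar macrophage-like cells had the alternative activation list at a median of 2.26 (2.18 to 2.46), percentile 100, with 13 of 14 members above 1.5-fold and 0 below. Its members Chil4, Retnla and Clec10a lay less than 2-fold above their B cell-like level, or above its floor where that was 0, and are read as background. Ccl17 was 4.76-fold (4.40 to 5.16) higher, Mmp12, a macrophage elastase, 4.83-fold (4.56 to 5.12) higher and the mannose receptor gene Mrc1 1.74-fold (1.64 to 1.85) higher. Aldh1a3, a retinaldehyde dehydrogenase, had 122 UMIs in DJ-1 KO OVA and 0 in WT OVA, at least 30.8-fold higher. Among markers of alveolar macrophages, Ear1 stood at 0.0511 (0.0377 to 0.0679), the lipid-binding protein gene Fabp1 at 0.0452 (0.0255 to 0.0748) and Siglecf at 0.239 (0.175 to 0.322) of the WT OVA level, while Chil3 was 1.81-fold (1.80 to 1.83) higher. Without the smaller cells the Fabp1 ratio was 0.0255. Fpr1, a formyl peptide receptor, stood at 0.0706 (0.0434 to 0.109). The eosinophil chemokine list had a median of 1.80 (1.68 to 1.90), percentile 100 in this class, with 6 of 9 members above 1.5-fold and 0 below, and the eosinophil granule and activation list -0.33 (-0.41 to -0.051), percentile 12.0. Most of these cells lay in cluster 11 in DJ-1 KO OVA (250 of 266), which Mmp12, Ccl24, Chil3 and Ccl17 lead, and in cluster 17 in WT OVA (132 of 172), which Ear1 leads.

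Alveolar type 2-like cells had inflammatory and NF-kB genes at a median of 1.73 (1.36 to 1.76), percentile 100, with 16 of 19 members above 1.5-fold and 0 below. Cxcl5, a neutrophil chemoattractant, was 21.7-fold (16.2 to 29.6) higher, Il4i1, an amino acid oxidase, 21.5-fold (11.2 to 46.0) higher, the costimulatory receptor gene Tnfrsf9 17.8-fold (14.1 to 22.8) higher and Lcn2, which binds siderophores, 3.33-fold (3.23 to 3.43) higher. Epithelial alarmins and their receptors had a median of 1.59 (1.04 to 2.02), percentile 99.9, and Il33, itself an alarmin, was 3.93-fold (3.72 to 4.14) higher. Mucous genes had a median of 0.78 (0.52 to 1.65), percentile 99.6 in this class, with Slc26a4 12.99-fold (11.7 to 14.5) higher. Clca1, Chil4 and Bpifb1 lay below their B cell-like level there and are read as background. Rab6b stood at 0.0710 (0.0190 to 0.187), the elongation factor gene Tcea3 at 0.126 (0.0694 to 0.212) and Serinc2 at 0.130 (0.0510 to 0.277) of the WT OVA level. In DJ-1 KO OVA 177 of 269 of these cells lay in cluster 16, which Slc26a4, Chia1, Il33 and Retnla lead, and in WT OVA 734 of 755 lay in cluster 5. Outside cluster 16 the ratios of DJ-1 KO OVA to WT OVA were 5.40 for Retnla and 3.52 for Slc26a4, while that of Ly6i was 0.652 (0.364 to 1.09) there and 2.88 in the whole class. Il33, Cxcl5 and Lcn2 are also among the leading genes of cluster 16, and their ratios outside it were not computed.

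Antioxidant and growth pathways in alveolar type 2-like cells differed less. NRF2 targets and antioxidant enzymes had a median of 0.24 (0.095 to 0.27), percentile 97.8, with 8 of 36 members above 1.5-fold and 4 below. Among them Gclc, the catalytic subunit that limits glutathione synthesis, was 2.72-fold (2.63 to 2.80) higher and Sod2, the mitochondrial superoxide dismutase, 2.44-fold (2.20 to 2.70) higher. Gclc is a leading gene of cluster 16, which held 177 of 269 of these cells in DJ-1 KO OVA and 21 of 755 in WT OVA. The Gclc ratio outside that cluster was not computed. The mTORC1, PI3K and AKT pathway had a median of 0.0013 (-0.17 to 0.10), percentile 15.01 and autophagy and mitophagy genes -0.070 (-0.17 to 0.015), percentile 3.98. In the latter list Pink1, a mitophagy kinase whose gene lies on the chromosome of Park7, stood at 0.488 (0.374 to 0.630). Progenitor genes had a median of 0.20 (0.078 to 0.28), percentile 88.7, which was -0.055 over members with at least 100 UMIs. Transitional state genes had a median of 0.58 (0.32 to 0.70), percentile 100. Surfactant and lipid genes had a median of -0.29 (-0.37 to -0.20), percentile 1.34, with Sftpc, a surfactant protein, at 0.700 (0.697 to 0.704) of the WT OVA level. Immediate early genes had a median of -0.48 (-0.55 to -0.41), percentile 0.0100, with 1 of 19 members above 1.5-fold and 8 below.

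Club-like cells, 71 in DJ-1 KO OVA and 99 in WT OVA, had Chil4 8.17-fold (7.91 to 8.45) higher and Sdf2l1, of the endoplasmic reticulum, 5.97-fold (3.91 to 9.35) higher. Retnlb, a resistin-like protein, had 180 UMIs in DJ-1 KO OVA and 0 in WT OVA, at least 119-fold higher. The urokinase receptor gene Plaur stood at 0.102 (0.0549 to 0.174), Ctgf, a matricellular protein, at 0.108 (0.0456 to 0.218) and the chemokine gene Ccl20 at 0.148 (0.108 to 0.1996) of the WT OVA level. The mucous list in this class had a median of 0.58 (0.53 to 0.68), percentile 100, and 5 settings turned it, to -1.84 with cells of at least 500 genes, -1.75 with doublets kept, -0.91 with at most 10% mitochondrial UMIs, -0.40 after thinning to 1000 UMIs and -0.14 with cells weighted alike, while it was 2.55 with each library clustered on its own. Goblet-like and club-like cells pooled gave 1.38. Most club-like cells of DJ-1 KO OVA lay in 2 sub-clusters, of 23 cells and of 19 cells that are all smaller members of pairs, and most of WT OVA in 2 others, of 37 and 26 cells. In all, 29 of the 71 club-like cells of DJ-1 KO OVA were smaller members of pairs, and 0 of the 99 of WT OVA.

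Fibroblast-like cells had the eosinophil chemokine list at a median of 1.25 (1.08 to 1.55), percentile 100, with 4 of 8 members above 1.5-fold and 0 below, with Ccl8 7.42-fold (4.51 to 12.8) higher. Thinning every cell to 1000 UMIs brought this median to -0.011, keeping doublets to 0.42 and a doublet score limit of 0.25 to 0.62. The collagen gene Col6a5 was 24.0-fold (10.6 to 66.9) higher, Saa3 7.68-fold (6.63 to 8.93) higher and Postn 3.26-fold (2.79 to 3.82) higher. Plac9b stood at 0.228 (0.164 to 0.310), Park7 at 0.265 (0.173 to 0.394) and Smoc1 at 0.285 (0.159 to 0.483) of the WT OVA level. Matrix and remodelling genes had a median of 0.38 (0.33 to 0.43), percentile 100. In CD4 T-like cells Rab4a was 3.34-fold (2.31 to 4.89) higher, Sytl1 3.09-fold (2.21 to 4.38) higher and Ubxn11, on chromosome 4 as is Park7, 3.06-fold (2.38 to 3.95) higher. Rell1 stood at 0.295 (0.213 to 0.402) of the WT OVA level there. Rab4a and Ubxn11 were higher in all 5 classes that could be compared, with median log2 ratios of 1.74 and 1.34. Neither difference is thus particular to CD4 T-like cells. Sub-cluster 0.2 of this class held 147 cells of DJ-1 KO OVA and 39 of WT OVA, and 2 others held 11 and 141 and 11 and 128. T helper 2 and regulatory T genes had a median of 0.31 (0.20 to 0.43), percentile 92.1, with Gata3, the T helper 2 regulator, 1.97-fold (1.73 to 2.24) higher.

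Shares of cells differed as well. Alveolar macrophage-like cells made up 5.92% (5.24 to 6.64) of DJ-1 KO OVA and 2.92% (2.504 to 3.38) of WT OVA. Goblet-like cells made up 1.33% (1.02 to 1.71) and 0.272% (0.155 to 0.441), ILC2-like cells 1.71% (1.35 to 2.14) and 0.866% (0.645 to 1.14), and cycling cells 5.56% (4.91 to 6.27) and 1.10% (0.852 to 1.40). The goblet-like log2 ratio was 2.30, but 0.62 with each library clustered on its own, 1.27 with doublets kept and 1.41 with at most 10% mitochondrial UMIs, and the ILC2-like one was 0.98, or 1.69 with each library clustered on its own. Of the 250 cycling cells of DJ-1 KO OVA, 152 lay in a cluster whose next-best score was that of the added Rag1 and Dntt list. Dntt stood at 570.4 CPM in cycling cells of DJ-1 KO OVA and 40.2 in those of WT OVA. Lower in DJ-1 KO OVA were alveolar type 2-like cells at 5.98% (5.31 to 6.72), neutrophil-like cells at 4.71% (4.11 to 5.37) and B cell-like cells at 7.23% (6.49 to 8.02), the last against 15.6% (14.7 to 16.6) in WT OVA. The neutrophil-like log2 ratio was -1.20, but -2.15 with at least 500 genes per cell and -0.84 outside the Rag1 and Dntt cluster and the cycling cells. Club-like cells made up 1.58% and 1.68%, or 0.949% and 1.68% without the smaller cells, and their log2 ratio was -0.090, or -1.09 with at least 500 genes per cell. Outside the Rag1 and Dntt cluster and the cycling cells, alveolar type 2-like cells made up 7.75% and 12.98%. The median log2 ratio of all genes was itself 0.24 in club-like, 0.14 in CD4 T-like and 0.10 in alveolar type 2-like cells, and for WT OVA over WT PBS 0.10 in club-like, 0.12 in CD4 T-like and -0.12 in alveolar macrophage-like cells, against which the medians above are to be read.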

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

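The tests of chance reuse of barcodes, of genes around Park7 as a set, of Hdac1 with Gm10093, of Park7 in the smaller DJ-1 KO OVA cells, of shared barcodes for type 2 linked genes and of cell numbers were chosen only after the result was seen. The test for mucous genes replaced one of Park7 in club-like and goblet-like cells, 0.162 (0.116 to 0.222) of the WT OVA level, since these held 75.7% of the mucous UMIs of DJ-1 KO OVA and 80% had been set.

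Barcodes, which no comparison of groups uses, occurred in both the WT PBS and the DJ-1 KO OVA library 372 times, where independent draws give 3.13 (upper limit 7), which argues against chance reuse. Of the genes detected in the smaller cell of a pair, a median of 99.0% were also detected in its partner, against 75.7% in random cells of the same class and depth. Park7 stood at 30.8 CPM (15.4 to 55.1) in the smaller WT PBS cells against 135 in the other WT PBS cells, and at 124 CPM (53.7 to 245) in the smaller DJ-1 KO OVA cells against 20.8 in the other DJ-1 KO OVA cells. These values are consistent with molecules of each library counted in the other. Where in library preparation or sequencing they may have crossed stays open, and no biological explanation was tested.

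Gm10093 stood at 42.2 CPM in DJ-1 KO OVA cells against 0.0441 in WT OVA and 0.203 in WT PBS (0.123 without the smaller cells), and Gm10036 at 49.8 CPM against 0.618 and 2.23 (0.946), genes that the ranking of named genes leaves out. Gm10093 resembles Hdac1, and Gm10036 Rpl11, genes on chromosome 4 as is Park7, and Hdac1 with Gm10093 summed had a log2 ratio of 0.14 where Hdac1 alone had -1.33, so reads moving between this gene and its copy may account for both. Rpl11 with Gm10036 summed stayed at -0.78 against -0.87 for Rpl11 alone, which argues against such movement as the whole cause of the lower Rpl11. Gm13157, Ubxn11 and Pink1, on the same chromosome, differed in each class compared, with median log2 ratios of -3.61, 1.34 and -0.97. Genes within 25 Mb of Park7 as a set reached percentile 96.9 of random gene sets (85.6 for WT OVA over WT PBS), short of the limit set, so DNA of another strain kept around the knockout allele and an effect of DJ-1 loss cannot be told apart for them, since both lie in 1 library.

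Type 2 and IL-13 linked genes were higher in DJ-1 KO OVA than in WT OVA. With both cells of each shared barcode left out, the alternative activation list in alveolar macrophage-like cells had a median log2 ratio of 2.51 (2.36 to 2.72). Type 2 cytokines over all kept cells had 1.78 (1.44 to 2.08). WT OVA and DJ-1 KO OVA shared 5 barcodes, where independent draws give 4.40, so copies in DJ-1 KO OVA would come mostly from WT PBS. That library held 20 Il13 UMIs and DJ-1 KO OVA 169, and all Ccl17 UMIs of its alveolar macrophage-like cells lay in smaller cells. Such copies could hardly raise these ratios, so the outcome was likely from the start and no conclusion on shared barcodes is drawn from it. Of a mucous member's DJ-1 KO OVA UMIs a median of 0.0711% (2.97% at most) lay in the smaller cells. The fold of the list needs 67.5%, but these cells held only 64371 of 17098133 UMIs, so a percent that high was unlikely from the start. Park7 stood at 23.4 CPM (19.8 to 27.4) in the larger DJ-1 KO OVA partner cells, below the 100.2 of WT OVA. With both cells left out the mucous list over all kept cells turned to -1.13, but that also removes those larger cells. The smaller cells thus add little to the mucous values, but no verdict on shared barcodes is drawn for these genes. In the alveolar classes, 20 gene and class values above 1.5-fold, of 18 genes, stood at a median of 6.58 times their B cell-like level, against free RNA as the cause for most, but 6 of them lay under 2 times. Within alveolar macrophage-like cells the alternative activation list stood at 2.26, which a larger class alone does not account for. A shift between clusters of that class was not separated from it, and no value within a cluster was computed. Cluster 11, which the list members Mmp12, Ccl24, Chil3 and Ccl17 help lead, held 250 of 266 such cells in DJ-1 KO OVA and 40 of 172 in WT OVA. Goblet cell numbers were not separated from the mucous list over all kept cells. A biological difference between these libraries, of genotype or of the mice pooled, may remain as a hypothesis, untested without replicates.

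The Rag1 and Dntt cluster held 17.3% of DJ-1 KO OVA cells, against 0.153% of WT OVA and 0.701% of WT PBS, and whether they belong to the lung was not tested.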

How the results depend on the processing

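The settings on shared barcodes, the doublet score limit of 0.25, the shares outside the Rag1 and cycling clusters and the pooling of club-like and goblet-like cells, with and without the smaller cells, were chosen only after the result was seen. Of 2129 alternative values for 164 results, 2024 kept their direction, 1705 lay within the counting interval and 37 reversed. No value of CPM without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes reversed, while 8 lay outside the counting interval in the same direction and 3 changed sign within it. Listed below are all reversed values and, of the main results only, those outside the counting interval, and 308 values of other results outside it are not listed. Some unlisted values changed direction outside the interval without being counted as reversed, among them 5 with each library clustered on its own. Values are log2 ratios, and lists are medians. Except where the setting itself removes the cells concerned, the cause was not tested. No paired analysis was possible because each group is 1 pooled library. A class with fewer than 10 cells under an alternative gave no value. Depth limits genes with few UMIs, such as Il4 with 7 UMIs in WT OVA, and median UMIs per cell differed from 1634 to 3852.5.

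At Leiden resolution 0.5, WT OVA over WT PBS moved for mucous list in club-like (1.21).

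At Leiden resolution 2, WT OVA over WT PBS reversed for Chil4 in club-like (-1.63), and moved for mucous list in club-like (0.50).

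With at least 500 genes per cell, WT OVA over WT PBS moved for the share of neutrophil-like (-0.59) and alternative activation in alveolar macrophage-like (0.76). DJ-1 KO OVA over WT OVA reversed for mucous list in club-like (-1.84), and moved for the share of club-like (-1.09), the share of neutrophil-like (-2.15) and eosinophil chemokines in fibroblast-like (1.76).

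With at most 10% mitochondrial UMIs, WT OVA over WT PBS reversed for Chil4 in club-like (-2.44) and mucous list in club-like (-0.088), and moved for the share of goblet-like (-1.19) and eosinophil chemokines in fibroblast-like (0.95). Under this setting DJ-1 KO OVA over WT OVA reversed for mucous list in club-like (-0.91), and moved for the share of goblet-like (1.41) and eosinophil chemokines in fibroblast-like (0.72).

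With both cells of each shared barcode left out, which also removes larger partner cells, WT OVA over WT PBS reversed for Ccl24 in alveolar macrophage-like (3.39), and moved for the share of alveolar macrophage-like (1.20), the share of club-like (1.90), alternative activation in alveolar macrophage-like (1.36), mucous list in club-like (1.21) and mucous list in all kept cells (5.25). The ratio of DJ-1 KO OVA to WT OVA reversed for Clca1 in all kept cells (-1.35), Muc5ac in all kept cells (-1.29) and mucous list in all kept cells (-1.13), and moved for the share of alveolar macrophage-like (0.66), the share of alveolar type 2-like (-1.47), the share of club-like (-2.95), the share of goblet-like (0.84), progenitor genes in alveolar type 2-like (0.076), alternative activation in alveolar macrophage-like (2.51) and type 2 cytokines in all kept cells (1.78).

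With cells thinned to 1000 UMIs, WT OVA over WT PBS reversed for Ccl17 in alveolar macrophage-like (-1.95), Chil4 in all kept cells (-3.50), Clca1 in all kept cells (-0.77), Muc5ac in all kept cells (-1.30) and mucous list in all kept cells (-0.77), and moved for NRF2 targets in alveolar type 2-like (0.27), alternative activation in alveolar macrophage-like (0.023), mTORC1 pathway in alveolar type 2-like (0.18) and mucous list in club-like (1.52). For the knockout comparison, values reversed for eosinophil chemokines in fibroblast-like (-0.011) and mucous list in club-like (-0.40), and moved for Park7 in all kept cells (-2.03), progenitor genes in alveolar type 2-like (-0.031), alternative activation in alveolar macrophage-like (1.84), mTORC1 pathway in alveolar type 2-like (0.10) and mucous list in all kept cells (1.91).

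With club-like and goblet-like cells pooled, WT OVA over WT PBS reversed for Chil4 in club-like (-0.36), and moved for mucous list in club-like (0.78). DJ-1 KO OVA over WT OVA moved for mucous list in club-like (1.38).

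With club-like and goblet-like cells pooled without the smaller cells, WT OVA over WT PBS moved for mucous list in club-like (1.22). Under this setting DJ-1 KO OVA over WT OVA moved for mucous list in club-like (1.39).

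With a doublet score limit of 0.25, WT OVA over WT PBS moved for eosinophil chemokines in fibroblast-like (0.70). The ratio of DJ-1 KO OVA to WT OVA moved for eosinophil chemokines in fibroblast-like (0.62).

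With doublets kept, WT OVA over WT PBS moved for the share of goblet-like (-1.14), eosinophil chemokines in fibroblast-like (0.75) and mucous list in club-like (0.25). For the knockout comparison, values reversed for mucous list in club-like (-1.75), and moved for the share of goblet-like (1.27) and eosinophil chemokines in fibroblast-like (0.42).

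With each library clustered on its own, WT OVA over WT PBS reversed for Chil4 in club-like (-4.83), Clca1 in club-like (-6.27), the share of classical monocyte-like (0.0047) and mucous list in club-like (-2.46), and moved for the share of alveolar type 2-like (1.22), the share of club-like (-0.71), the share of goblet-like (-0.32), the share of ILC2-like (1.00) and alternative activation in alveolar macrophage-like (0.042). DJ-1 KO OVA over WT OVA moved for the share of alveolar macrophage-like (0.52), the share of goblet-like (0.62), the share of ILC2-like (1.69), alternative activation in alveolar macrophage-like (2.60) and mucous list in club-like (2.55).

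With the mean over cells of CPM, WT OVA over WT PBS reversed for Ccl17 in alveolar macrophage-like (-2.59), Ch25h in alveolar macrophage-like (-0.11), Chil4 in all kept cells (-3.79), Clca1 in all kept cells (-1.09), Muc5ac in all kept cells (-1.22), alternative activation in alveolar macrophage-like (-0.60), eosinophil chemokines in alveolar macrophage-like (-0.48), eosinophil granule genes in alveolar macrophage-like (0.13), mucous list in all kept cells (-0.95) and transitional state in alveolar type 2-like (-0.19), and moved for progenitor genes in alveolar type 2-like (0.052), mucous list in club-like (1.44) and type 2 cytokines in all kept cells (0.64). Under this setting DJ-1 KO OVA over WT OVA reversed for mucous list in club-like (-0.14), and moved for Park7 in fibroblast-like (-1.33), alternative activation in alveolar macrophage-like (1.93) and mucous list in all kept cells (1.505).

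With median-of-ratios scaling, WT OVA over WT PBS moved for NRF2 targets in alveolar type 2-like (0.028). The ratio of DJ-1 KO OVA to WT OVA moved for mucous list in club-like (0.33).

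Over members past the background rule, WT OVA over WT PBS moved for eosinophil chemokines in fibroblast-like (0.91). For the knockout comparison, values moved for progenitor genes in alveolar type 2-like (-0.059), alternative activation in alveolar macrophage-like (2.08) and eosinophil chemokines in fibroblast-like (1.04).

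Over members with at least 100 UMIs, WT OVA over WT PBS moved for progenitor genes in alveolar type 2-like (0.10). DJ-1 KO OVA over WT OVA moved for progenitor genes in alveolar type 2-like (-0.055) and type 2 cytokines in all kept cells (0.77).

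Among cells outside the Rag1 and cycling clusters, DJ-1 KO OVA over WT OVA reversed for the share of fibroblast-like (0.13), and moved for the share of alveolar macrophage-like (1.37), the share of alveolar type 2-like (-0.74) and the share of neutrophil-like (-0.84).

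As a share of immune or of other cells, WT OVA over WT PBS moved for the share of alveolar type 2-like (0.62). Under this setting DJ-1 KO OVA over WT OVA reversed for the share of fibroblast-like (0.28), and moved for the share of alveolar type 2-like (-0.60) and the share of club-like (0.41).

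Without the smaller cell of each shared barcode, WT OVA over WT PBS reversed for Ccl24 in alveolar macrophage-like (3.69) and the share of goblet-like (3.38), and moved for the share of alveolar macrophage-like (1.05), the share of club-like (0.49), alternative activation in alveolar macrophage-like (1.38) and mucous list in all kept cells (2.04). The ratio of DJ-1 KO OVA to WT OVA moved for the share of club-like (-0.83).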

Other observations

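The tracing of type 2 cytokine UMIs to cell classes was chosen only after the result was seen, and the other values come from the lists fixed before. In DJ-1 KO OVA, γδ T-like cells held 72 of 169 Il13 UMIs and ILC2-like cells 65, and in WT OVA they held 2 and 5 of 11. In WT PBS ILC2-like cells held 19 of 20. Il13 stood at 243 CPM in γδ T-like cells of DJ-1 KO OVA and 5.16 CPM in those of WT OVA. The same cells held 23 of 49 Il4 UMIs and 19 of 80 Il5 UMIs in DJ-1 KO OVA. Gata3 stood there at 1148 CPM, against 469.9 in WT OVA, and Il17a at 297 against 238. Il5 came mostly from ILC2-like cells, with 40 of 40 UMIs in WT PBS, 50 of 62 in WT OVA and 43 of 80 in DJ-1 KO OVA. The parting of these classes moves with clustering, since DJ-1 KO OVA held 118 γδ T-like and 77 ILC2-like cells, and 63 and 108 at Leiden resolution 0.5. The γδ T-like cluster had 4 of its markers detected and a score of 3.81, with CD4 T next at 1.71. Whether CD4 T cells within it carry these cytokines was not tested.

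Lists outside the allergic response are given here for DJ-1 KO OVA over WT OVA. In alveolar type 2-like cells interferon response genes had a median log2 ratio of 0.94 (0.67 to 1.08), percentile 100, oxidative phosphorylation genes 0.32 (0.29 to 0.40), percentile 100 and heat shock genes 0.55 (0.44 to 0.61), percentile 99.9. Cell cycle genes over all kept cells had 1.26 (1.14 to 1.37), percentile 100, where 152 DJ-1 KO OVA cells and 3 WT OVA cells lay in the cycling cluster that also scores for Rag1 and Dntt. In alveolar macrophage-like cells MHC class II genes had 0.21 (0.16 to 0.30), percentile 89.1, glycolysis and hypoxia genes 0.17 (0.049 to 0.38), percentile 93.8 and inflammatory and NF-kB genes -0.26 (-0.33 to -0.043), percentile 8.01.

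For WT OVA over WT PBS, alveolar type 2-like cells had interferon response genes at 0.30 (0.14 to 0.50), percentile 98.1, inflammatory and NF-kB genes at 0.48 (0.37 to 0.53), percentile 100, oxidative phosphorylation genes at 0.078 (0.016 to 0.12), percentile 24.1 and heat shock genes at 0.49 (0.36 to 0.56), percentile 100. Cell cycle genes over all kept cells had 0.075 (-0.011 to 0.13), percentile 71.6. In alveolar macrophage-like cells MHC class II genes had 0.55 (0.48 to 0.73), percentile 99.9, inflammatory and NF-kB genes 0.40 (0.32 to 0.58), percentile 100 and glycolysis and hypoxia genes 0.12 (-0.019 to 0.19), percentile 95.8.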
